A study of Streptomyces avermitilis with 4 samples.

How the data were processed

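RNA from mycelia was extracted with Trizol and made into Illumina libraries, per the labels' protocols. The series holds 4 libraries of strain S0, 2 collected on day 4 and 2 on day 8. A single table of the whole series holds a row per gene with, per library, an estimated count and an FPKM value, both deposited by the authors. Bowtie2 2.2.3 is the one tool named, per the submitters' processing notes; the counter, the genome build, the annotation and any use of strand are not given in the sources used here. Per the file headers the columns are counts and FPKM. The estimated counts deposited by the authors are not scaled between libraries, and 9.08% to 9.61% of them are not whole, so reads that match several genes were shared out. The FPKM values deposited by the authors are divided by a length that is shorter than the gene by a median of 216 to 233 bp among genes of at least 1 kb. The authors' deposited table also holds, per the file headers, a log2 fold change, a p-value and an adjusted p for day 8 against day 4, where 924 genes have no log2 fold change or p-value and 922 have no adjusted p.

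The gene identifiers of the table did not match any identifier of the reference annotation supplied for the species, so names come only from the Swiss-Prot matches in the table, with e-values up to 9.94e-06. A name is that of the best match and not an assignment of the gene, and 4802 genes have no match. Coordinates and strand are those of the table, 1-based, and the genes are coding sequences only. No ribosomal or transfer RNA gene is listed, so the share of reads on them is unknown.

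Counts were rounded to whole numbers. Genes were kept by edgeR's default filter, scaled by TMM (factors 0.961 and 1.01 for day 4, 1.02 and 1.01 for day 8), and tested by edgeR's quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The biological coefficient of variation was 12.2%. CPM values use TMM-scaled totals of the genes tested. Log2 fold changes are day 8 over day 4. Gene lists, 43 in all, were fixed before the data were examined and matched on symbol or product text. The 35 lists with at least 5 tested members were tested with limma's camera on log2 CPM (prior count 2, preset correlation 0.01), adjusted over the lists. Since the lists match names, some hold genes that only act on the named process. The tests used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

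Named genes were chosen by a rule fixed before the data were examined: the largest changes among genes past the threshold, of which there were none; every avermectin cluster gene, of which none carries a name in the table; for each list discussed the members with the largest changes past the threshold, or the member with the highest mean; and the 5 genes with the highest mean on each day. The RNA polymerase subunits and the 3 genes called in the authors' deposited table were named in addition, after their values were seen. Of the lists, 24 are described with their member of highest mean and 11 by their values alone, a choice made after the data were seen, and 8 were not tested, for want of members.

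The steps were tested on simulated counts drawn for this comparison from the real means and library sizes, with 8460 genes tested. Of 100 genes changed 2-fold, 84 were called, and of 100 changed 4-fold, 99 were called, with 11 unchanged genes called. Of 35 lists, 1 was called, the list raised 1.5-fold. Totals of 2205864 to 2288633 counts per library set the depth. The simulation holds no library that stands apart, gives all genes the same dispersion and draws them independently. Its rates therefore do not carry over to the real libraries, for genes or for lists.

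Alternatives fixed before the data were examined were the replicate number as a block, DESeq2's size factors, library totals alone, DESeq2 in place of edgeR, no count filter, at least 50 counts in 2 libraries, a test against a fold of 2, an estimated correlation or fry for lists, and leaving out each library in turn. Those planned for tables without counts were not run. After the data were seen, mirrored pairs were summed (946 pairs), the replicate numbers were crossed, and the trend of each library with gene level was removed by lowess (span 0.3). A pair is exact where both ends mirror, and near where at least 50% of a gene overlaps a mirrored gene.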

Results

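Transcript levels were deposited for mycelia of strain S0 of Streptomyces avermitilis, a filamentous soil bacterium known as the producer of avermectins, on day 4 and day 8 of a fermentation that the labels call P3. The series sets these days against each other, with 2 libraries of day 4 and 2 of day 8. The table lists 10151 protein-coding genes, and 5349 of them carry a best Swiss-Prot match, which is the source of the gene names used here. Estimated counts summed to 2206772 and 2278465 for replicates 1 and 2 of day 4, and to 2205864 and 2288633 for replicates 1 and 2 of day 8. Of all genes, 819 had no count in any library, including 556 of the 557 genes of at most 150 bp. Nothing in the labels says that the replicates are separate cultures, so p-values measure only the spread between these samples, which may be technical. No gene could be assigned to the avermectin, oligomycin or filipin clusters from the names in the table, so no level is given for them.

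Most genes lay close to a common level in every library. Among the 2734 genes of at least 1 kb, the median was 163 and 176 FPKM in replicates 1 and 2 of day 4, and 178 FPKM in each library of day 8. The share of these genes within 2-fold of their library's median was 84.7% and 92.5% at day 4, and 96.3% and 94.2% at day 8. The highest of them reached 720 FPKM in replicate 1 of day 4, or 4.41 times that library's median, and between 473 and 484 FPKM in the other libraries. Growing bacteria usually transcribe ribosomal protein genes strongly. The 38 genes of at least 300 bp matched by name to ribosomal proteins lay below genes of like length. They include rimO, which encodes a modifying enzyme, and how many others do so was not counted. Their median ratio was 0.420 and 0.580 in the day-4 libraries and 0.690 and 0.646 in the day-8 libraries.

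**Figure D1:**
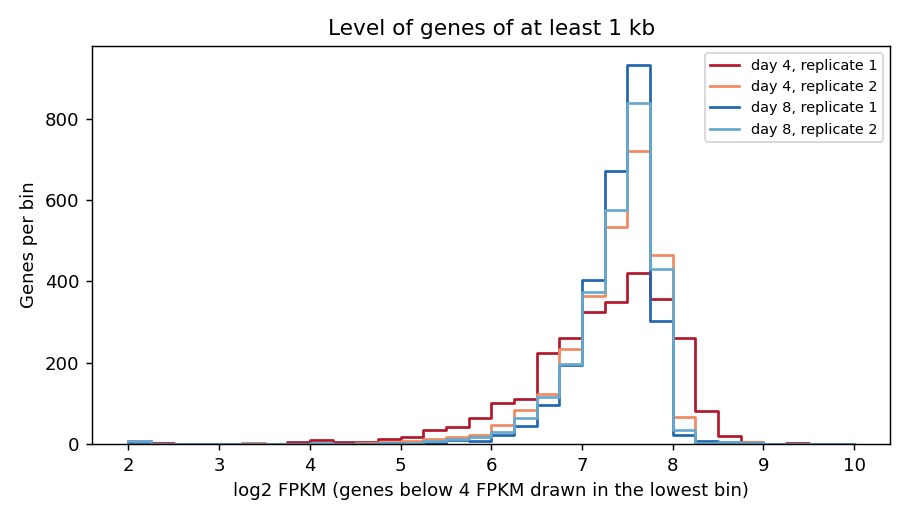
Number of genes of at least 1 kb (vertical axis, genes per bin) by log2 FPKM (horizontal axis) in each of the 4 libraries. The medians lie between 163 and 178 FPKM, and the distribution of replicate 1 of day 4 is the widest, with 84.7% of genes within 2-fold of the median.

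The reference sequence of the table, whose build is not given in the sources used here, carries the same genes at both ends. The first 953707 bp and the stretch from 8677659 to 9631365 mirror each other, with 888 gene pairs at exactly mirrored positions and 58 pairs that overlap a mirrored position in part. All 888 exact pairs had equal counts in every library, within 0.01, so each member holds a share of the reads of a sequence given 2 times. Genes of the arms are therefore uncertain as single copies. Ratios for the arms below use this share per copy, so they do not show that the sequence has fewer reads than the middle. Among genes of at least 500 bp, the median count per kilobase of the arms (1039 genes) was 0.759 and 0.801 of that of the middle (5256 genes) at day 4, and 0.880 and 0.866 at day 8. A terminal segment from 9632235 to 9723830, with 50 genes of that length, had a median of 1.67 and 1.71 times the middle at day 4, and 1.55 and 1.48 times at day 8. For both ratios the smallest p that an exact two-sided permutation test of 2 against 2 libraries can give is 0.333.

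**Figure D2:**
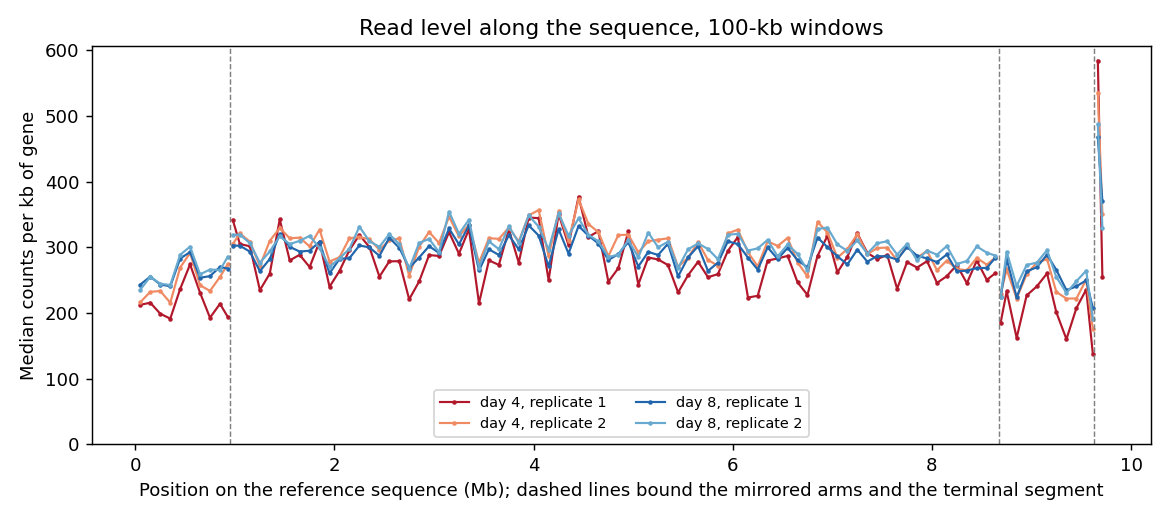
Median estimated count per kilobase of gene (vertical axis) in windows of 100 kb along the reference sequence (horizontal axis, Mb) for each library, drawn separately for the mirrored arms, the middle and the terminal segment. Arm genes are drawn with each copy's share of the reads. Over whole regions the arms have 0.759 to 0.880 of the middle's median and the terminal segment 1.48 to 1.71 times it, while the second of its 2 windows has 254 in replicate 1 of day 4, below that library's median of 280 in the middle.

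At the level of single genes, no change between day 4 and day 8 passed the test. By edgeR's quasi-likelihood test, 0 of 8448 tested genes had an adjusted p under 0.05, and the smallest adjusted p was 0.369. At an unadjusted p under 0.05 there were 1121 genes, 611 higher and 510 lower at day 8, where chance alone gives 422. DESeq2 called 3 genes and had 595 at an unadjusted p under 0.05. The estimated log2 fold changes had a median of -0.003 and quartiles of -0.20 and 0.21, and 98.2% of tested genes lay within 1 of 0. For 51.8% of tested genes both day-8 libraries lay on the same side of both day-4 libraries, where chance gives 33.3%. Genes vary together across libraries, so this share is not a test of the day. An exact two-sided permutation test of 2 against 2 libraries cannot give a p under 0.333. The test called 68 genes without replicate 1 of day 4, 3545 without replicate 2 of day 4, 12 without replicate 1 of day 8 and 14 without replicate 2 of day 8. Nearly all genes called without 1 or the other library of day 8 were partly mirrored genes, which share reads with a partner. So were many of those called without replicate 1 of day 4, and few of those without replicate 2 of day 4. Replicate 1 of day 4 stood apart from the rest: the SD over genes of its log2 CPM differences from the other libraries was 0.46 to 0.58, against 0.31 to 0.34 among the other 3 libraries.

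The genes with the most reads on both days were long genes that match modular polyketide synthases, the assembly lines of many antibiotics. The 5 highest genes were the same on day 4 and day 8, and each has an erythronolide synthase (eryA) as its best match. The e-values of these matches run from 1.37e-26 for NEAU-XAVGM000703 to 2.23e-07 for NEAU-XAVGM005338, and the class of the genes rests on them alone. NEAU-XAVGM000703 (518380 to 532200) and its mirrored copy NEAU-XAVGM009555 each had 2739 ± 309 CPM at day 4 and 2591 ± 18.7 CPM at day 8 (mean ± SD, n = 2 per day). NEAU-XAVGM000720 (558839 to 570208) and its copy NEAU-XAVGM009537 each had 1983 ± 44.0 and 2049 ± 48.7 CPM. NEAU-XAVGM005338 (5167868 to 5176213), in the middle of the sequence, had 2059 ± 303 CPM at day 4 and 1676 ± 72.6 CPM at day 8, with a log2 fold change of -0.30 ± 0.16 (SE) and an adjusted p of 0.394 by edgeR. That value was -0.14 without replicate 1 of day 4 and -0.44, with an adjusted p of 1.8e-06, without replicate 2 of day 4. These CPM values are not divided by gene length, and the coding lengths of the genes are 13821, 11370 and 8346 bp.

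In the authors' deposited table, 3 genes had an adjusted p under 0.05 for day 8 against day 4, 2 of them higher and 1 lower at day 8. All 3 lie in the right mirrored arm and have a partner of slightly different length in the left arm. In the authors' deposited table the adjusted p was 0.00763 for NEAU-XAVGM009344 (8845441 to 8847177, best match poxB, a pyruvate dehydrogenase), 0.00763 for NEAU-XAVGM009851 (9380324 to 9383287, no match) and 0.0210 for NEAU-XAVGM009217 (8712391 to 8713671, no match). DESeq2 here gave the same 3 genes. The poxB-like gene had counts of 0.36 and 443 at day 4 and 0.05 and 0.38 at day 8, so its mean at day 4 comes from replicate 2 alone, while its partner NEAU-XAVGM000912 had 1144 and 910.0 at day 4 and 1343 and 1339 at day 8. NEAU-XAVGM009851 had counts of 0.01 and 0.04 at day 4 and 371 and 0.04 at day 8, so its mean at day 8 comes from replicate 1 alone. NEAU-XAVGM009217 had 327 and 321 at day 4 and 739 and 535 at day 8, while its partner NEAU-XAVGM001041 had 380 and 493 at day 4 and 66.1 and 288 at day 8. By edgeR the log2 fold change of NEAU-XAVGM009217 was 0.93 ± 0.17 (SE) with an adjusted p of 0.369. The count filter left the other 2 genes untested there. After the counts of mirrored partners were summed, a setting chosen after the data were seen, the log2 fold changes of the 3 pairs were 0.07, 0.39 and 0.07 by edgeR, and DESeq2 called 0 of 8493 genes, with 615 at an unadjusted p under 0.05.

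**Figure D3:**
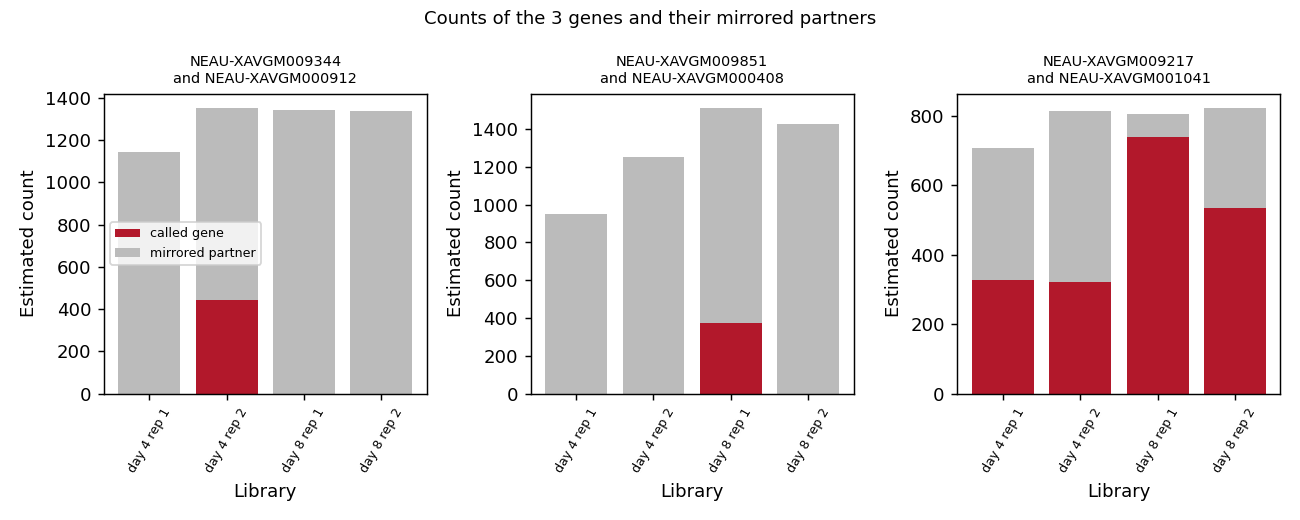
Estimated counts (vertical axis) per library (horizontal axis) of the 3 genes with an adjusted p under 0.05 in the authors' deposited table, stacked on those of their mirrored partners. The summed height of the pair with NEAU-XAVGM009217 runs from 707 to 823, while the gene alone runs from 321 to 739.

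Among gene groups, 5 of 35 tested lists were called by limma's camera with a preset correlation, all higher at day 8: transposases, RNA polymerase subunits, ribosomal proteins, cytochrome oxidases with the bc1 complex, and ATP-dependent proteases. Each of these calls was lost with an estimated correlation, where the adjusted p was 0.696 for all 5. That was the smallest camera adjusted p of any of the 35 lists in this setting, whose correlations come from only 4 libraries. The simulation did not check whether this setting can call a raised list, so the loss alone does not decide against a list. In each of the 5 called lists the day-4 libraries themselves differed, with replicate 1 below replicate 2 by a median of 0.18 to 0.67 on the log2 scale. Against replicate 2 of day 4 alone, day 8 was higher by a median of 0.19 for transposases and 0.26 for RNA polymerase subunits. For ribosomal proteins it was 0.10, for cytochrome oxidases 0.17 and for proteases 0.14. Without replicate 1 of day 4, transposases were the only list called, with a camera adjusted p of 0.000155, and the other 4 lists had 0.0528 to 0.201. Of the lists, 7 had no member in the table and 1, storage lipid synthesis, had 3 tested members, with a median log2 fold change of -0.27.

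Transposases, the enzymes that move insertion elements, were the list with the smallest p. Their 61 tested members had a median log2 fold change of 0.31 (SD 0.27 between members), with 49 members above 0 and 12 below, a camera adjusted p of 1.61e-07, and an adjusted p of 0.696 with an estimated correlation. No member passed over all genes, and 0 passed adjusted over the list alone. In the mirrored arms lie 56 of the 61, so the members above and below 0 and the camera test count both copies of mirrored genes. With mirrored pairs summed, a setting chosen after the data were seen, the list has 33 members and a camera adjusted p of 1.23e-05. The member with the highest mean, NEAU-XAVGM000118 (best match tnpB), had 218 ± 9.65 CPM at day 4 and 215 ± 8.90 CPM at day 8 (mean ± SD, n = 2 per day), a log2 fold change of -0.02 ± 0.12 (SE) that turns to 0.02 with library totals alone.

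RNA polymerase subunits had the largest shift of the called lists. The 5 tested members had a median log2 fold change of 0.55 and all lay above 0, with a camera adjusted p of 0.0207 and an adjusted p of 0.696 with an estimated correlation. Of the members, 0 passed over all genes and 5 passed adjusted over the list alone. They are 4 distinct genes, since rpoA2 is listed in both arms, and 4 is fewer than the 5 members asked of a list. The beta' subunit gene rpoC (2789239 to 2793138), the member with the highest mean, had 273 ± 56.4 CPM at day 4 and 367 ± 15.5 CPM at day 8, a log2 fold change of 0.43 ± 0.15 (SE) and an adjusted p of 0.369 by edgeR. The others were named after their values were seen: the beta subunit gene rpoB had a log2 fold change of 0.47, the alpha subunit gene rpoA 0.55 and rpoA2, a further alpha subunit, 0.55. Without replicate 1 and without replicate 2 of day 4, the log2 fold changes were 0.23 and 0.66 for rpoC, 0.17 and 0.85 for rpoB, 0.46 and 0.63 for rpoA, and 0.25 and 0.94 for rpoA2, and by edgeR all 4 genes passed without replicate 2 and none without replicate 1. For rpoB, replicates 1 and 2 of day 4 had 153 and 244 CPM, and those of day 8 had 282 and 271 CPM.

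Ribosomal proteins (39 tested members) had a median log2 fold change of 0.28 with an SD of 0.56 between members, 28 above 0 and 11 below. Their camera adjusted p was 0.0298, and the adjusted p was 0.696 with an estimated correlation. The member with the highest mean was rimO, which encodes an enzyme that modifies a ribosomal protein and is not one itself, at 110 ± 12.8 CPM and 128 ± 11.5 CPM. Cytochrome oxidases and the bc1 complex, which end the respiratory chain (16 members, median 0.28, 13 above 0), had a camera adjusted p of 0.0357 and an adjusted p of 0.696 with an estimated correlation. The member with the highest mean was a match to cydD, a transporter needed for cytochrome assembly. It had 632 ± 125 CPM on day 4 and 522 ± 22.9 CPM on day 8, against the direction of the list. Its log2 fold change of -0.28 was -0.06 without replicate 1 and -0.46 without replicate 2 of day 4. ATP-dependent proteases and the proteasome (15 members, median 0.32, 12 above 0) had a camera adjusted p of 0.0357 and an adjusted p of 0.696 with an estimated correlation. The Lon protease gene had 363 ± 13.3 CPM and 360 ± 20.7 CPM. In these 3 lists 0 members passed over all genes and 0 passed adjusted over the list alone. Without replicate 1 or replicate 2 of day 8 the protease list was no longer called, with camera adjusted p of 0.115 and 0.0794.

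**Figure D4:**
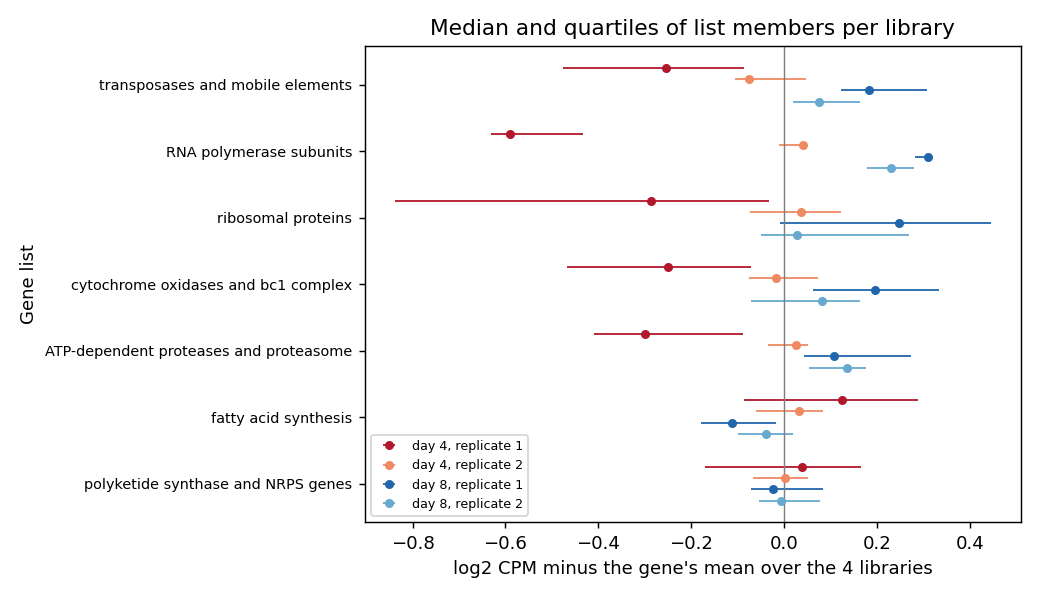
Median over list members (points) with quartiles (bars) of the log2 CPM minus each gene's mean over the 4 libraries (horizontal axis), per list (vertical axis) and library. RNA polymerase subunits lie at -0.59 in replicate 1 of day 4, 0.04 in replicate 2 of day 4, and 0.31 and 0.23 at day 8.

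Genes of secondary metabolism did not pass as lists. The polyketide synthases and nonribosomal peptide synthetases (83 tested members) had a median log2 fold change of -0.03 and a mean of 0.00, 36 above 0 and 47 below, with a camera adjusted p of 0.691. The list matches product text, so it holds 0 of the 51 genes whose match is named erythronolide synthase, including the 5 highest genes above. Of the 94 genes of the list in the table, 65 lie in the mirrored arms. The member matching a mycobacterial phenolphthiocerol synthase, NEAU-XAVGM000718 (551886 to 558692), had 1083 ± 69.0 CPM at day 4 and 1180 ± 22.0 CPM at day 8, the highest mean of the list. Pentalenolactone genes (9 members, an antibiotic of the terpenoid class) had a median of 0.42 and an adjusted p of 0.136, with a median difference of 0.26 between the day-4 libraries and 0.08 between day 8 and replicate 2 of day 4, and the pentalenene oxygenase match ptlI had 142 ± 1.62 CPM and 151 ± 8.29 CPM. Ectoine synthesis, which makes a solute that protects against osmotic stress (8 members), had a median of 0.45, with 0.22 between the day-4 libraries and 0.14 between day 8 and replicate 2 of day 4, an adjusted p of 0.140, 0 members past the test over all genes and 3 adjusted over the list alone. Its gene ectB, NEAU-XAVGM007449, had 102 ± 22.8 CPM and 150 ± 6.40 CPM, a log2 fold change of 0.56 ± 0.17 (SE) and an adjusted p of 0.369 by edgeR, and is 1 of those 3. Its log2 fold change was 0.35 without replicate 1 and 0.82 without replicate 2 of day 4. The other 2, named after their values were seen, are a short ectB match and its mirrored copy, NEAU-XAVGM000514 and NEAU-XAVGM009746, each with 12.6 ± 2.14 CPM and 23.6 ± 0.673 CPM. The carotenoid list (7 members, of which 2 are enoyl-CoA hydratases caught by their symbol crt) had a median of 0.08, a mean of 0.00 and a test direction downward, with an adjusted p of 0.996 and a direction that flips with library totals alone. Its phytoene dehydrogenase match crtI had 242 ± 7.57 CPM and 257 ± 5.72 CPM. Siderophore synthesis and uptake (13 members), which serves iron supply, had a median of 0.05 and a camera adjusted p of 0.743. Its median was -0.04 between day 8 and replicate 2 of day 4. An rhbC match in this list had 385 ± 34.0 CPM and 342 ± 30.4 CPM. In the polyketide, pentalenolactone, carotenoid and siderophore lists 0 members passed over all genes and 0 passed adjusted over the list alone.

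Lists for the supply of acyl building blocks did not pass either. Fatty acid synthesis (35 members) had a median log2 fold change of -0.11, 26 members below 0 and 9 above, and a camera adjusted p of 0.0635. The enoyl reductase match fabL had 335 ± 87.1 CPM at day 4 and 269 ± 3.41 CPM at day 8. Fatty acid degradation (67 members) had a median of 0.06 and an adjusted p of 0.268, with the acyl-AMP ligase match fadD28 at 797 ± 110 CPM and 622 ± 13.4 CPM. Branched-chain amino acid breakdown and methylmalonyl-CoA supply, which feeds polyketide synthesis (32 members), had a median of 0.16 and a camera adjusted p of 0.140. Its member with a best match to a methylcrotonoyl-CoA carboxylase subunit (e-value 1.83e-12) had 437 ± 57.2 CPM and 376 ± 18.5 CPM.

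Energy metabolism and growth lists outside the 5 called had positive medians, which were smaller or below 0 against replicate 2 of day 4 alone. Translation factors (15 members) had a median of 0.30, with 0.28 between the day-4 libraries and 0.09 between day 8 and replicate 2 of day 4, and a camera adjusted p of 0.0651, and an elongation factor G gene matching fusB had 426 ± 19.5 CPM and 375 ± 5.78 CPM. ATP synthase (9 members) had a median of 0.15, with 0.23 between the day-4 libraries and -0.02 between day 8 and replicate 2 of day 4, and an adjusted p of 0.456, with atpA at 130 ± 22.5 CPM and 169 ± 2.82 CPM. The respiratory NADH dehydrogenase (30 members) had a median of 0.13, with 0.30 and 0.02 for the same differences, and an adjusted p of 0.140, with a nuoL match at 361 ± 27.2 CPM and 331 ± 12.0 CPM. The TCA cycle (28 members) had a median of 0.09, with 0.16 and 0.05 for these differences, and an adjusted p of 0.203, with a match to a fumarate reductase subunit at 555 ± 43.3 CPM and 506 ± 2.69 CPM.

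Nitrogen assimilation (46 members) had a median of 0.06 and a camera adjusted p of 0.505, with the glutamate synthase match gltB at 631 ± 65.1 CPM and 698 ± 28.3 CPM. Phosphate starvation genes (13 members) had a median of 0.30 and a camera adjusted p of 0.129. The polyphosphate kinase gene ppk had 251 ± 65.3 CPM and 309 ± 26.7 CPM. Its log2 fold change was 0.05 without replicate 1 and 0.60 without replicate 2 of day 4. Glycoside hydrolases and chitin degradation (93 members) had a median of 0.10 and an adjusted p of 0.0651, with a lacZ match at 567 ± 22.0 CPM and 524 ± 11.2 CPM. Aerial hyphae and spore formation, the developmental program of Streptomyces (23 members), had a median of -0.03 and an adjusted p of 0.571, with a spoVK match at 673 ± 137 CPM and 547 ± 27.2 CPM. Sigma and anti-sigma factors (76 members) had a median of 0.08 and an adjusted p of 0.140, with the phosphatase match rsbP at 391 ± 39.2 CPM and 414 ± 3.16 CPM. Oxidative stress defence (37 members) had a median of 0.15 and an adjusted p of 0.419, with the thioredoxin reductase match trxB at 210 ± 4.00 CPM and 240.5 ± 14.3 CPM. Chaperones (23 members) had a median of 0.19 and a camera adjusted p of 0.196, with clpB1 at 324 ± 24.9 CPM and 370 ± 8.05 CPM. Against replicate 2 of day 4 alone, the median at day 8 was 0.03 for nitrogen, 0.22 for phosphate, 0.05 for glycoside hydrolases and -0.05 for spore formation. It was 0.08 for sigma factors, 0.08 for oxidative stress and 0.06 for chaperones. In the nitrogen, phosphate, glycoside hydrolase, spore, sigma factor, oxidative stress and chaperone lists, and in the fatty acid, branched-chain, energy and growth groups, 0 members passed over all genes and 0 passed adjusted over the list alone. The other 11 tested lists are given by median log2 fold change and camera adjusted p: aminoacyl-tRNA synthetases 0.16 and 0.112, glycolysis 0.08 and 0.641, the pentose phosphate pathway 0.04 and 0.999, arginine synthesis 0.13 and 0.268, glycogen and trehalose 0.11 and 0.268, gas vesicles 0.21 and 0.517, cell division 0.08 and 0.344, DNA replication 0.11 and 0.283, cytochromes P450 0.13 and 0.199, TetR-family regulators 0.01 and 0.797, and genes matching the left chromosome arm 0.19 and 0.268. The last of these lists matches names and not positions, and 2 of its 5 tested members lie in the mirrored arms. Between day 8 and replicate 2 of day 4 the median was -0.03 for glycolysis, -0.01 for the pentose phosphate pathway, -0.08 for gas vesicles and -0.003 for cell division. In these 11 lists 0 members passed over all genes, and adjusted over the list alone 1 passed, the P450 gene NEAU-XAVGM002664, with 50.9 ± 5.98 CPM and 87.8 ± 9.69 CPM, named after its values were seen. Over all 30 lists not called, 27 had a median log2 fold change above 0 and 3 below, while against replicate 2 of day 4 alone 8 had a median below 0, and the camera adjusted p ran from 0.0635 to 0.999.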

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

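The settings with mirrored pairs summed, crossed numbers or the level trend removed, and the tests on them, were chosen after the results were seen. edgeR called 0 genes, and also 0 with DESeq2 size factors, library totals alone, no count filter, at least 50 counts in 2 libraries, a test against a fold of 2, and mirrored pairs summed. DESeq2 called 3 genes and, with mirrored pairs summed, 0. The labels do not say that equal replicate numbers pair samples, and the deviations of equally numbered libraries had a correlation over genes of -0.12. With the replicate block 29 genes were called, 13 of them partly mirrored genes, and 14 with mirrored pairs summed and the block. With the numbers crossed as a block, 78 genes were called. Leaving out 1 library, with the lone library of that day assumed to vary like those of the other day, gave 12 to 3545 calls, the highest without replicate 2 of day 4. The cause of these changes was not tested. Nearly all calls without 1 or the other library of day 8 were partly mirrored genes. Alternatives planned for normalized values were not run, since the table holds counts.

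Of the lists, 5 were called, also 5 with library totals alone and 5 with the replicate block, where the protease list had an adjusted p of 0.0543 and translation factors 0.0430. With mirrored pairs summed 4 of 33 lists were called, since RNA polymerase then has too few members. With an estimated correlation 0 were called, with fry 0, with the level trend removed 1, with the trend removed and an estimated correlation 0, and without 1 library 1 to 7. Over these settings the adjusted p ran from 2.35e-07 to 0.999 for transposases, 0.00875 to 0.999 for RNA polymerase, 8.21e-05 to 0.999 for ribosomal proteins, 0.00912 to 0.999 for cytochrome oxidases and 0.0272 to 0.999 for proteases. The cause was not tested for the block, the estimated correlation and fry.

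With the level trend removed the direction turned for cytochrome oxidases (adjusted p 0.822), ATP synthase (0.858), NADH dehydrogenase (0.857), spore formation (0.999), glycoside hydrolases (0.999), oxidative stress (0.999) and carotenoids (0.677), and for the same 7 lists at 0.999 with an estimated correlation as well. Carotenoids also turned with library totals alone (0.878), with fry (0.974) and without replicate 1 of either day (0.677 to 0.838 over the libraries left out), and siderophores without replicate 1 of day 4, with 0.601 to 0.969 over the libraries left out. Polyketide synthases turned upward without replicate 1 of day 8, with an adjusted p of 0.791 to 0.969 over the libraries left out. For genes with a log2 fold change near 0 the sign turned as follows, and the cause was not tested. NEAU-XAVGM000118 had 0.0198 and the lon gene 0.0257 with library totals alone. Without 1 library, NEAU-XAVGM000118 ran from -0.0690 to 0.0270, lon from -0.0717 to 0.0380, rsbP from -0.0167 to 0.182, and NEAU-XAVGM000703 and its copy from -0.191 to 0.0344. Of the other values for named genes under other settings, 368 kept direction and side of the threshold and 30 passed it, 23 of these without replicate 2 of day 4.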

Other observations

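All tests of explanations below were chosen after the results were seen. Fold changes differed by region of the reference, and the medians moved closer together once the trend of each library with gene level was removed. The median log2 fold change was 0.13 over 1486 tested arm genes, with 66.6% above 0, -0.03 over 6872 genes of the middle, with 46.3% above 0, and -0.29 over 90 genes of the terminal segment, with 23.3% above 0. With the level trend removed, the median log2 differences were 0.04 in the arms, with 59.6% above 0, -0.01 in the middle, with 47.6% above 0, and 0.05 in the terminal segment, with 55.6% above 0. For arm genes the level used was that of a single copy, with its share of the reads. A hypothesis is that the terminal segment is the linear plasmid SAP1 known from the type strain of the species, placed at the end of the reference. Of its 107 coding lengths, 69 equal that of a SAP1 gene in the reference annotation of strain MA-4680, against a median of 17 and at most 29 when 97 chromosomal genes drawn at random took the place of the 97 SAP1 genes (1000 draws), which is consistent with that hypothesis. No sequence was compared.

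Most genes lay at nearly the same level, where the transcripts of a bacterium usually span a wide range. Scaling of the counts by the authors is argued against, since at least 88.4% of the genes of at least 1 kb have a whole count in every library, where scaled counts would seldom be whole. Genomic DNA among the sequenced fragments may account for part of it, and stays open. The genes matched by name to ribosomal proteins reached at most 0.690 times the level of genes of like length. DNA would place them within 2-fold, but in replicate 1 of day 4 their 0.420 lies below that range. A library evened by nuclease treatment was not tested, and no biological explanation was tested.

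The 3 genes called in the authors' deposited table each share reads with a mirrored partner. The counts of the genes alone are not whole, while 12 of the 12 sums with the partner, of 3 pairs in 4 libraries, are whole within 0.005. An uneven split of these reads between both copies may account for the calls, but was not tested against a change of a single copy between days. NEAU-XAVGM009344 had 0.36 and 443 in the replicates of day 4, and NEAU-XAVGM009851 had 371 and 0.04 in those of day 8. A change of a single copy between days does not by itself account for such a difference within a day. For NEAU-XAVGM009217 that change stays open, since the sum with the other copy can hide it.

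The 4 called lists other than transposases may reflect replicate 1 of day 4 rather than the day. The difference between the day-4 libraries was a median of at least 0.23 on the log2 scale in each, larger than that between the other day-4 library and day 8. A trend with gene level between libraries is a candidate explanation too, over 6345 genes of at least 500 bp (Spearman's rho across genes, which are not independent replicates). The difference of replicate 1 from replicate 2 of day 8 ran against the level in replicate 2 of day 4 (rho -0.39). That of replicate 1 from replicate 2 of day 4 followed the level in replicate 2 of day 8 (rho 0.66). With that trend removed the smallest adjusted p of the 4 lists was 0.619, and the calls ended because the shifts shrank: the mean log2 difference (SD between members) went from 0.54 (0.06) to 0.13 (0.12) for RNA polymerase, 0.36 (0.55) to 0.02 (0.39) for ribosomal proteins, 0.27 (0.29) to -0.05 (0.16) for cytochrome oxidases and 0.26 (0.27) to 0.01 (0.15) for proteases. A change with the day stays open, as untested apart from these.

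For transposases 3 technical explanations stay open. As set, the tests of the level trend and of the arms counted a p under 0.05 against the explanation. At the preset correlation both came out against it. They are left open because the shift shrank with the trend removed and because of the estimated correlation, neither of which was part of those tests. With the level trend removed the list was still called at the preset correlation (adjusted p 0.00186), but its mean log2 difference went from 0.31 (SD 0.26) to 0.09 (SD 0.17), and the adjusted p was 0.999 with an estimated correlation. As for the arms as a whole, 28 transposase genes among 785 arm genes with pairs summed had a median of 0.32 (SD 0.28) and the others 0.14, with p = 0.0124 by camera at the preset correlation and p = 0.441 with an estimated correlation. With the trend also removed these medians were 0.13 (SD 0.17) and 0.04, with p = 0.0442 and, with an estimated correlation, p = 0.277. In both removals of the trend, the level of an arm gene was the FPKM of a single copy, which holds only a share of the reads. Whether the smaller shift depends on that was not tested. The arms do not account for the 5 members in the middle, which have whole counts in every library and all lay above 0, with a median of 0.31 (SD 0.29) against -0.03 in the middle as a whole. For reads shared between copies, 54 of the 61 members had counts that were not whole in at least 1 library. The 7 with whole counts in every library, all above 0 with a median of 0.21, gave a camera adjusted p of 0.0555. Whole counts do not mark unshared genes, since equal shares can be whole. Besides the 5 in the middle, these 7 include members in the mirrored arms, so the test does not isolate unshared members. The test as first set counts a value of 0.05 or more as fitting shared reads, and 7 members were judged too few to decide only after the value was seen. A change with the day stays open too.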
